A study of Homo sapiens with 6 samples.

How the data were processed

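Total RNA of human glioma cells was hybridized as biotin-labelled cRNA to 6 Affymetrix expression arrays, 3 for U87 and 3 for U87-2M1. The deposited values are intensity values, a MAS5 signal per probe set on a linear scale, per the submitters' processing notes; the software version, scaling target and detection calls are not given in the sources used here. The table held 54675 probe sets with no missing value, from 0.0132 to 16784, and all 6 columns were matched to samples. The 2% trimmed means of the arrays ran from 22.1 to 53.5, so no common scaling between arrays was in the values.

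The plan written before the data were examined assumed that the authors had scaled the arrays, and fitted the deposited values as they stood. Because the columns were not on a common scale, the main setting became quantile normalization between arrays over the probe sets that are not controls, which had been listed beforehand as another setting and was chosen from the column distributions before any test. The fit on unscaled values is given beside the main counts. Quantile normalization equalizes the distributions and so cannot show a change of total RNA per cell.

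Probe sets were named from the platform annotation supplied for this work. A single gene symbol was found for 41091 probe sets, several for 1801 and none for 11721, leaving out 62 control probe sets. Of those with a single symbol, 41037 matched the RefSeq gene table by Entrez ID, and 0 symbols needed an update. Each of 19775 genes was represented by its probe set with the highest mean over all 6 arrays. In the other settings this choice was made anew, so a gene's value there can come from another of its probe sets. Where other probe sets of a named gene lay above the filter, they were compared; for 2 of 139 named genes, RECK and PGF, at least 1 moved the opposite way at an unadjusted p below 0.05. Values were transformed as log2(value + 16), and genes above the 40th percentile of the mean, 4.61 on that scale, were tested, 11865 in all. Differences and folds are on this scale, which understates the change of dim genes. Of the named genes, 16 had a group mean below that level, where the size of a difference depends on the pseudocount. The number of arrays limits the precision.

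Differences were tested with limma (lmFit and eBayes with an intensity trend, two-sided) and Benjamini-Hochberg adjusted p-values, with a threshold of 0.05. The prior held 7.8 degrees of freedom beside 4 residual ones. Errors of differences are moderated standard errors, and errors of group levels are standard deviations of 3 arrays. Fixed gene lists (35, with 997 genes, of which 914 had a probe set) were written before the data were examined and tested with limma's camera (inter-gene correlation preset to 0.01, with a trend) where at least 5 genes were tested, which held for 33 lists; Benjamini-Hochberg adjustment ran over these. Counts adjusted over the list alone used the members' p-values only. The lists were the hypoxia response, glycolysis, oxidative phosphorylation, matrix metalloproteinases and inhibitors, other invasion proteases, collagens, matrix glycoproteins and proteoglycans, integrins and adhesion receptors, mesenchymal transition, epithelial junction, motility and cytoskeleton, the TGF-beta, Wnt and Notch pathways, growth factors and receptor tyrosine kinases, angiogenesis factors, inflammatory cytokines and chemokines, interferon response, antigen presentation, mitosis, DNA replication, p53 targets, unfolded protein and amino acid response, cholesterol and lipid synthesis, oxidative stress and metal response, heat shock, neural stem and proneural genes, astrocyte and glia, lung epithelium, endothelium, blood and immune cells, fibroblast, cancer testis antigens, HOX genes and housekeeping genes. List genes without a single-symbol probe set were not analysed here.

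Genes were named by a rule set before the data were examined: the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap; from each list up to 4 members past the threshold with the largest absolute difference, or where none passed the 1 member with the largest; and a fixed set of genes always given (VEGFA, SLC2A1, MMP2, MMP9, CD44, VIM, CDH2, GFAP and NES among them). CA9 was in that fixed set too but had no probe set with a single gene symbol. Further members are named where few members of a list went the stated way, and are said to be named after their values were seen.

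Other settings written before the data were examined were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, median centring, the mean of a gene's probe sets, leaving out probe sets marked as shared (suffix _x_at or _s_at), no intensity trend, a replicate block, each array left out in turn and, for lists, camera with an estimated correlation and fry. Unscaled values were the main fit of the plan and became another setting once the column distributions had been seen. Scaling by 2% trimmed means and scaling on 9 hybridization spike-in probe sets were added after seeing the data. Where a scaling moved the median of all genes by over 0.1, genes and lists were compared relative to that median. The chromosome of each gene and the order along it came from the RefSeq gene table of a later genome assembly. They were used for the chromosome medians and their matched draws, for neighbouring genes, for stretches of genes and for the simulated chromosome shift.

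The procedure was tested on simulated arrays with the real means and spreads and unequal gains, in which 200 genes were changed singly, 41 more as a list shifted by -0.5 and 164 more as a chromosome shifted by 0.3; 11865 genes passed the filter. Of 67 genes changed by a log2 of 0.5, 13.4% were recovered, of 67 changed by 1, 46.3%, and of 66 changed by 2, 71.2%, and 1 of 11477 unchanged genes was called. The shifted list reached an adjusted p of 4.6e-27 (camera) with the preset correlation and 0.042 with an estimated one, and the median of the shifted chromosome was 0.29. The simulated noise was independent between genes. The simulation therefore cannot show how correlated genes affect the list calls or the number of false calls in the real arrays. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.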

Results

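Transcript levels were measured in U87 cells, an established human glioma line grown in vitro, and in U87-2M1, a subline of it. Per the labels, U87-2M1 was recovered after an experimental lung metastasis assay in vivo, kept under hypoxia and used at passage 4, whereas the U87 cells were at a late passage. Each group had 3 arrays. Subline, passage and oxygen therefore differed together, and the comparison is between the 2 groups as a whole. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The deposited intensities were not on a common scale: the 2% trimmed mean of an array was 22.1 to 25.9 in U87 and 36.5 to 53.5 in U87-2M1. After quantile normalization, correlations between arrays were 0.967 to 0.968 within U87, 0.966 to 0.981 within U87-2M1 and 0.946 to 0.956 between the groups. The 5′ to 3′ signal ratio of GAPDH, a sign of RNA integrity, was 0.577 to 0.597 in U87 and 0.634 to 0.874 in U87-2M1, so it moved with the groups and with every gene group described here. That of actin overlapped, at 0.0921 to 0.102 and 0.0683 to 0.193. It was at most 0.193 on all 6 arrays, so in both groups the 5′ end of actin gave far less signal than its 3′ end. Whether other genes share this was not tested.

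The subline carried higher transcripts of many matrix proteins and of cancer testis antigens, and lower transcripts of the DNA replication machinery. As lists these were called with a preset correlation between genes and not with an estimated one (adjusted p = 0.097 with an estimated correlation for matrix glycoproteins and for DNA replication, 0.12 for collagens and 0.10 for cancer testis antigens), and the DNA replication call was also lost without scaling and the cancer testis call without shared probe sets. Single matrix-degrading enzymes went both ways. THBS1, a secreted matrix glycoprotein that regulates cell adhesion, rose from near the floor of the scale, and THBS2, a relative of it, fell to that floor, so no fold is given for either. On the log2(value + 16) scale CCL2, a chemokine that attracts monocytes, was 15.5-fold higher and the collagenase MMP1 7.62-fold higher, and the stromelysin MMP3 was 4.00-fold lower. VEGFA, the main angiogenic growth factor and a target of hypoxia-inducible factors, was 2.10-fold lower in the subline. Of 11865 genes tested, 1071 were higher and 803 lower at an adjusted p below 0.05 (limma, two-sided, Benjamini-Hochberg), 1874 in all. Of these, 260 were at least 2-fold higher and 112 at least 2-fold lower, and 47 against 2 passed 4-fold. These counts depend on the pseudocount: with 1 in place of 16, 456 were higher and 260 lower at 2-fold and 141 against 31 at 4-fold, and with 64, 87 and 33 at 2-fold and 16 against 0 at 4-fold. Groups did not overlap for 35.5% of the tested genes, where chance gives 10%.

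On the log2(value + 16) scale the largest rise was that of APCDD1L, at 5.54 ± 0.40 in U87 and 10.05 ± 0.28 in U87-2M1 (mean ± SD, n = 3 each), a difference of 4.51 ± 0.20 (SE, limma adjusted p = 7.82e-08). PARM1 rose by 4.47 ± 0.15 (SE, adjusted p = 1.34e-08) from 4.10 ± 0.04, a level at the floor of the scale, while its other probe set had 2.22, so the size of its rise is uncertain. THBS1, CDH11, HPGD, LINC00922 and TMEM132D-AS1 also started near that floor, at 4.21 to 4.41, and rose by 3.24 to 3.76. The order depends on the pseudocount: with a pseudocount of 1, TMEM132D-AS1 (6.25), HPGD (5.48), THBS1 (5.46) and LINC00922 (5.39) rose by more than APCDD1L (5.08). The other genes among the 10 largest rises were KRTAP1-5 (4.11 ± 0.20), CCL2 (3.96 ± 0.17) and MAGEC1 (3.34 ± 0.20). CDH11 is a cadherin of mesenchymal cells, and HPGD is the enzyme that inactivates prostaglandins. On the same scale the 10 largest falls were smaller. With a pseudocount of 1, THBS2 (-4.79) and HMGN3 (-4.00), which end at or near the floor, changed by more than MAGEC1 (3.95), and THBS2 by more than KRTAP1-5 (4.58). PARM1 had 2.90 in that setting, in which the brightest probe set was chosen anew. A smaller pseudocount cannot lower the difference of a single probe set, so 2.90 belongs to its other probe set and gives it no rank here. THBS2 went from 6.17 ± 0.22 to 4.10 ± 0.08, a difference of -2.07 ± 0.18 (adjusted p = 1.84e-05), and MMP3 from 11.71 ± 0.02 to 9.71 ± 0.14 (adjusted p = 5.72e-08). LOC101927166, EDIL3, EVI2A, CDCA7, PTGES, SCD5, HMGN3 and IL11 had differences from -1.98 to -1.76. The fall of SCD5 was called in 11 of 18 other settings (adjusted p 9e-06 to 0.7), and its other probe set had -0.28, so it is uncertain. PTGES, which makes prostaglandin E, was 3.70-fold lower, opposite in direction to HPGD.

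**Figure D1:**
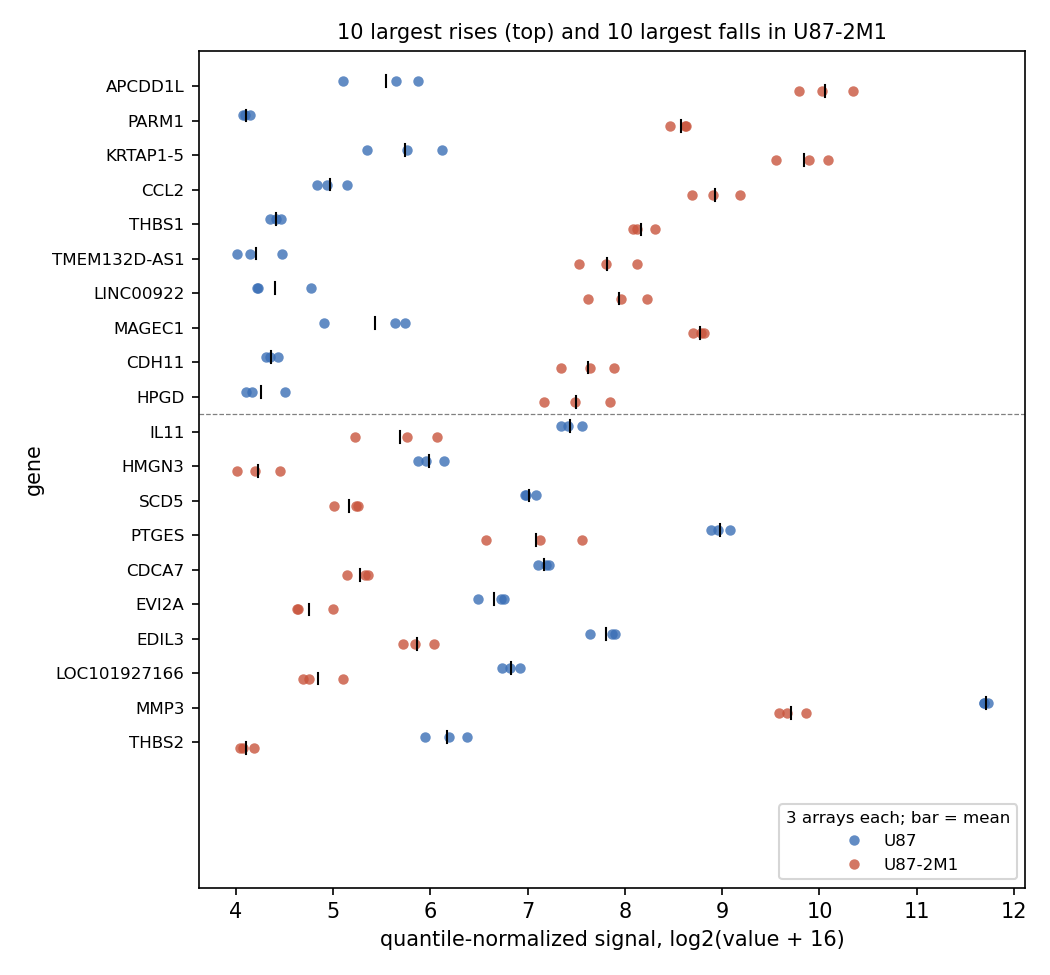
Quantile-normalized signal (x axis, log2(value + 16)) of the 10 genes with the largest rise and the 10 with the largest fall in U87-2M1 (y axis). Each point is an array (3 per group) and each bar a group mean; no point of a group overlaps the other group, and PARM1 goes from 4.10 to 8.57.

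Transcripts of the extracellular matrix rose as a group. Of 32 tested matrix glycoproteins and proteoglycans, 16 rose, 3 fell and 13 did not pass (20 and 3 when adjusted over the list alone), with a median log2 difference of 0.48 (camera adjusted p = 1.8e-05; adjusted p = 0.097 with an estimated correlation). Besides THBS1, the laminin chain LAMA4 rose by 2.46 ± 0.15 (SE) and CCN2, a matricellular growth modulator, by 1.57 ± 0.18. The 3 that fell were THBS2, SPP1 and TNFAIP6, the last 2 of these named after their values were seen. Of 17 collagen genes, 8 rose and 1 fell (9 and 1 when adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.00016; adjusted p = 0.12 with an estimated correlation). COL8A1 rose by 1.65 ± 0.13 and COL6A1, a beaded-filament collagen, by 1.61 ± 0.13. The collagen I chains went apart: COL1A2 rose by 0.92 ± 0.09, and COL1A1, named after its values were seen, had a difference of -0.80 ± 0.20 (adjusted p = 0.0199).

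Proteases and adhesion receptors were compared as 3 lists. Of 23 invasion proteases and their inhibitors outside the metalloproteinases of the matrix, 7 rose and 1 fell (10 and 1 when adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.0055; adjusted p = 0.12 with an estimated correlation). PLAU, the urokinase activator of plasminogen, rose by 2.60 ± 0.10, SERPINE2, an inhibitor of such proteases, by 1.45 ± 0.10 and the collagen-cleaving cathepsin CTSK by 1.14 ± 0.14, while ADAM12 had a difference of -1.54 ± 0.14. The matrix metalloproteinases and their inhibitors showed no common direction: of 16, 3 rose and 3 fell (3 and 4 when adjusted over the list alone; camera adjusted p = 0.86). MMP1 rose by 2.93 ± 0.12 and the inhibitor TIMP2 by 1.42 ± 0.13, whereas MMP3 fell and RECK, a membrane inhibitor, had a difference of -1.45 ± 0.14. Another 2 probe sets of RECK moved the opposite way at an unadjusted p below 0.05, so its direction is uncertain. MMP2 and MMP9, the gelatinases, had differences of 0.01 ± 0.15 and -0.22 ± 0.20 (adjusted p = 0.966 and 0.497). Of 25 integrins and adhesion receptors, 6 rose and 1 fell, also when adjusted over the list alone (median 0.25; camera adjusted p = 0.014; adjusted p = 0.13 with an estimated correlation). ITGB8 rose by 1.03 ± 0.20, ICAM1 by 0.99 ± 0.15 and ITGA2, a collagen receptor chain, by 0.89 ± 0.14; the neural adhesion molecule NCAM1 had a difference of -1.47 ± 0.20. ITGB8 in U87 and NCAM1 in U87-2M1 lay near the floor, and with a pseudocount of 1 they had 2.22 and -2.81. CD44, the hyaluronan receptor, had -0.08 ± 0.08 (adjusted p = 0.533). Without shared probe sets, without scaling or with median centring the calls of the proteases (highest adjusted p 0.069) and the integrins (0.3) were lost, the latter also without a filter or with spike-in scaling.

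Genes tied to mesenchymal and neural progenitor states rose in part. Of 16 mesenchymal transition genes, 6 rose and 3 fell (6 and 4 when adjusted over the list alone), with a mean of 0.63 and a median of 0.20 (camera adjusted p = 0.017; adjusted p = 0.14 with an estimated correlation). CDH11, CHI3L1 (3.05 ± 0.17), S100A4 (2.81 ± 0.22) and ACTA2, smooth muscle actin (1.01 ± 0.15), rose. The transcription factors SNAI2 and ZEB2 and the receptor AXL, named after their values were seen, fell, with differences of -0.76, -0.64 and -0.69. VIM, the intermediate filament of mesenchymal cells, and CDH2 had differences of 0.07 ± 0.06 and 0.23 ± 0.15 (adjusted p = 0.467 and 0.311), and VIM was called lower with 2% trimmed mean scaling (-0.23, adjusted p = 0.04; 0.04 to 0.95 over its other settings) and lay below 0 with spike-in scaling. Of 29 neural stem and proneural genes with a probe set, only 10 reached the level needed for testing. Of these 10, 4 rose and none fell (6 and 0 when adjusted over the list alone), with a median of 0.57 (camera adjusted p = 0.0049; adjusted p = 0.12 with an estimated correlation). NES, the filament of neural progenitors, rose by 1.69 ± 0.19, SOX9 by 0.84 ± 0.16, PDGFRA by 0.80 ± 0.21 from near the floor and GAP43 by 0.60 ± 0.17. The call of this list was lost without a filter or without shared probe sets (highest adjusted p 0.57), and that of the mesenchymal list without U87-2M1 replicate 1 (0.052). Over its settings the median of the neural stem and proneural list ran from -0.003 to 0.77, so its shift depends on which members are tested. GFAP lay below the level needed for testing, at 4.08 and 4.17. Of 22 cancer testis antigens with a probe set, mostly germline genes that tumours can express, only 10 reached the level needed for testing. That level is a mean over all 6 arrays, so a gene can reach it through its high group alone. Among the 10, 7 rose and 1 fell, also when adjusted over the list alone (median 0.94, camera adjusted p = 7.3e-05, or 0.10 with an estimated correlation). MAGEC1, MAGEA6 (3.15 ± 0.21), MAGEA12 (2.37 ± 0.22) and SSX1 (1.27 ± 0.16) rose, and PNMA2, named after its values were seen, had a difference of -1.07. Near-identical MAGE and SSX copies can share probes, so single members are uncertain, and the list's call was lost without probe sets marked as shared (camera adjusted p = 0.075). The size of the list's shift is uncertain too, as its median ran from 0.032 to 1.2 over its settings.

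Genes of DNA replication and mitosis were compared as separate lists. Of 43 DNA replication genes, 18 fell and 1 rose (23 and 1 when adjusted over the list alone), with a median of -0.47 (camera adjusted p = 9.5e-07; adjusted p = 0.097 with an estimated correlation). Differences were -0.90 ± 0.13 for MCM3 and -0.86 ± 0.13 for MCM6, parts of the replicative helicase, -0.82 ± 0.12 for UHRF1, which maintains DNA methylation, and -0.80 ± 0.11 for TYMS, thymidylate synthase. RPA2, named after its values were seen, rose by 0.49. Of 36 mitosis genes, 6 fell and 1 rose (7 and 1 when adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.0025; adjusted p = 0.12 with an estimated correlation). MAD2L1, a spindle checkpoint protein, had a difference of -1.15 ± 0.18, ASPM -0.94 ± 0.19 and the cyclin CCNA2 -0.86 ± 0.13, while HMMR, named after its values were seen, rose by 0.50. The mitosis list moved to 0.01 relative to all genes without scaling or with median centring, where its call was lost (adjusted p = 0.76 and 0.63), as with spike-in scaling (0.64). The DNA replication list lost its call without scaling or with median centring (adjusted p = 0.069 and 0.056) but stayed lower, with a median of -0.51 to -0.28 over its settings. Of 22 p53 targets, 4 rose and none fell, also when adjusted over the list alone (median 0.29; camera adjusted p = 0.014; adjusted p = 0.13 with an estimated correlation): RRM2B (1.07 ± 0.13), ZMAT3 (1.04 ± 0.14), CCNG1 (0.97 ± 0.15) and TP53INP1 (0.74 ± 0.22). The canonical targets CDKN1A and MDM2, named after their values were seen, had 0.35 and 0.28 without passing (adjusted p = 0.167 and 0.185). Of 13 HOX genes, 3 fell and none rose, also when adjusted over the list alone (median -0.29; camera adjusted p = 0.014; adjusted p = 0.20 with an estimated correlation). The HOX genes that fell were HOXC4 (-0.78 ± 0.24, close to the threshold at a limma adjusted p of 0.0466), HOXD8 (-0.76 ± 0.15) and HOXC6 (-0.62 ± 0.16). Their list's call was lost without a filter, without shared probe sets or without U87 replicate 3 (highest adjusted p 0.085).

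**Figure D2:**
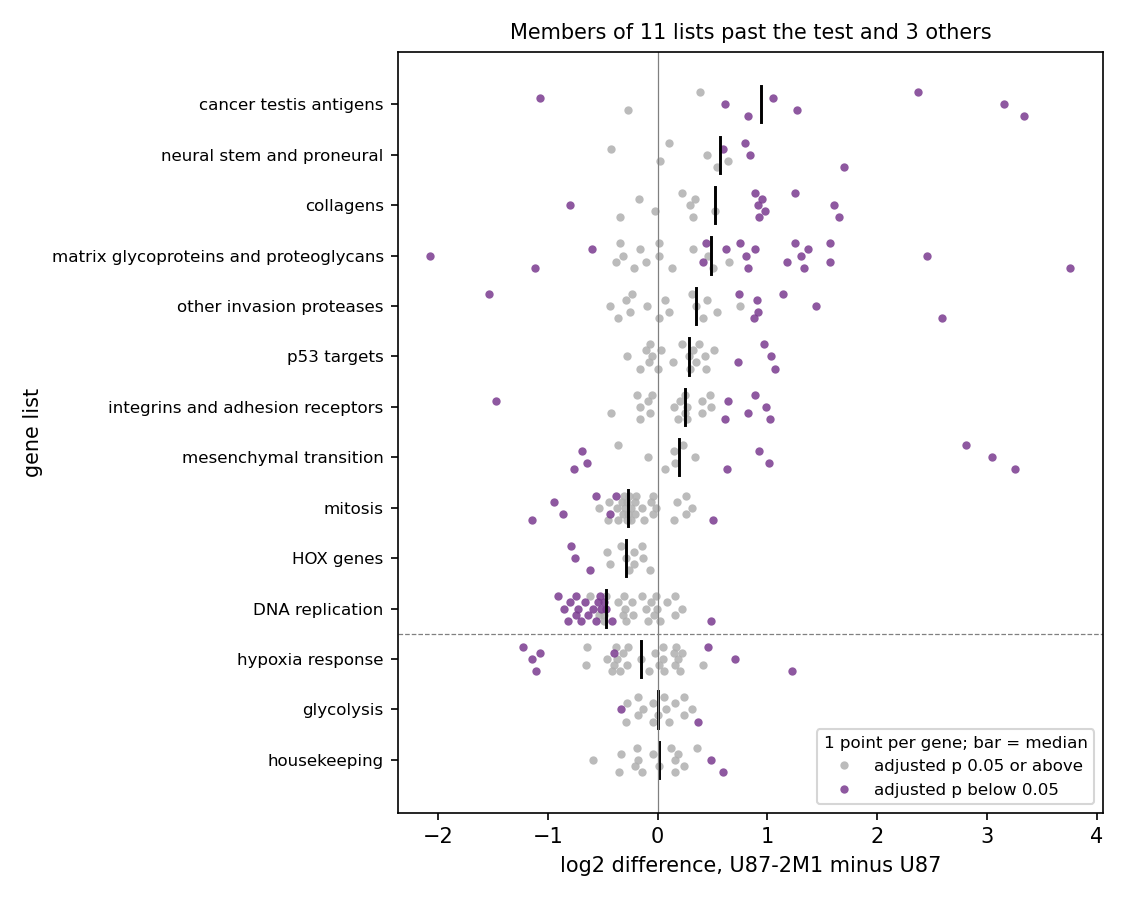
Log2 difference between U87-2M1 and U87 (x axis) of each tested member of the 11 lists past the test and of the hypoxia response, glycolysis and housekeeping lists (y axis). Purple points passed an adjusted p of 0.05 and bars are list medians, which run from 0.94 for cancer testis antigens to -0.47 for DNA replication.

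Because the subline had been kept under hypoxia, genes that low oxygen induces were compared. Of 33 hypoxia response genes, 3 rose, 5 fell and 25 did not pass (4 and 7 when adjusted over the list alone). CA9, also on that list, had no probe set with a single gene symbol and was not analysed. The list's median was -0.15 (-0.27 without U87-2M1 replicate 1) and it was not past the test (camera adjusted p = 0.099; adjusted p = 0.22 with an estimated correlation), although fry, which does not compare the list with other genes, gave a lower direction at an adjusted p of 0.00045. LOX, which crosslinks collagen, rose by 1.22 ± 0.16 (SE), with STC2 and ADM, named after their values were seen, at 0.71 and 0.46. The 5 that fell were NDRG1 (-1.23 ± 0.15), CA12 (-1.14 ± 0.13), DDIT4 (-1.11 ± 0.14), VEGFA (-1.07 ± 0.09) and BNIP3 (-0.40 ± 0.08), the last named after its values were seen. SLC2A1, the main glucose transporter of many tumours, had -0.41 ± 0.16 (adjusted p = 0.0979). Of 17 glycolysis genes, PFKP rose by 0.37 ± 0.11 and LDHA had -0.33 ± 0.06, also when adjusted over the list alone; the median was 0.001 and the mean 0.006, while camera gave a lower direction (adjusted p = 0.79). The glycolysis list passed as higher than other genes with median centring and without scaling (0.13 in both; adjusted p = 0.023 and 0.04; 0.023 to 0.98 over its other settings). Both settings leave the U87-2M1 arrays brighter, which with the pseudocount raises bright genes by more than dim ones. That pass therefore does not show a rise of glycolysis. Of 41 genes of oxidative phosphorylation, 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.79), among them COX4I1 at 0.64 ± 0.11 and ATP5ME at -0.77 ± 0.13.

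Secreted signals changed in both directions. Of 30 growth factors and receptor tyrosine kinases, 10 rose and 3 fell (10 and 4 when adjusted over the list alone; camera adjusted p = 0.092). HGF, the ligand of the MET receptor, rose by 2.92 ± 0.16 and IGFBP4, which binds insulin-like growth factors, by 1.54 ± 0.25, and EFNB2 had -1.55 ± 0.14. IGFBP4 started at 4.65 in U87, just above the level needed for testing, so the size of its rise is uncertain. Of 18 angiogenesis factors, 4 rose and 2 fell (5 and 2 when adjusted over the list alone; camera adjusted p = 0.36). The lymphangiogenic factor VEGFC rose by 1.51 ± 0.13 and SEMA3A, from near the floor, by 1.23 ± 0.24 (2.87 with a pseudocount of 1), while PGF had -0.89 ± 0.15. The other probe set of PGF had 2.56 and the mean of both was called higher (0.84, adjusted p = 0.03; 3.5e-05 to 0.1 over its other settings), so its direction is uncertain. Of 21 inflammatory cytokines and chemokines, 4 rose and 8 fell (4 and 9 when adjusted over the list alone; camera adjusted p = 0.093), with CCL2 and TNFAIP2 (1.85 ± 0.19) higher and IL11 (-1.76 ± 0.20) and CXCL2 (-1.13 ± 0.10) lower. In the TGF-beta pathway, 6 of 27 rose and 3 fell (8 and 4 when adjusted over the list alone; camera adjusted p = 0.22), led by BMP2 (2.00 ± 0.20) and the antagonists FST (1.95 ± 0.14) and GREM1 (1.37 ± 0.15). In the Wnt pathway, 3 of 22 rose and 3 fell, also when adjusted over the list alone (median -0.06, mean 0.11; camera adjusted p = 0.79). The Wnt antagonist family members DKK3 (2.73 ± 0.14) and DKK1 (1.13 ± 0.17) rose, and CCND1 had -0.98 ± 0.17. In the Notch pathway, 3 of 10 rose and 1 fell, also when adjusted over the list alone (median -0.15, mean 0.05; camera adjusted p = 0.84), with JAG1 at 0.68 ± 0.14 and NOTCH2 at -0.59 ± 0.12. Of 38 motility and cytoskeleton genes, 7 rose and 2 fell (7 and 5 when adjusted over the list alone; camera adjusted p = 0.42), including TPM1 at 1.34 ± 0.08.

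The other metabolic, stress and immune lists did not pass in the main setting. Of 22 cholesterol and lipid synthesis genes, 1 rose and 4 fell (3 and 5 when adjusted over the list alone; camera adjusted p = 0.099), with INSIG1 at -1.48 ± 0.13 and SCD, a fatty acid desaturase, at -1.33 ± 0.14. Of 31 genes of the unfolded protein and amino acid response, 2 rose and 6 fell (3 and 7 when adjusted over the list alone; camera adjusted p = 0.28). HSPA5, an endoplasmic reticulum chaperone, rose by 1.02 ± 0.08, whereas the serine synthesis enzymes PSAT1 and PHGDH had -1.33 ± 0.13 and -1.01 ± 0.19. Of 20 antigen presentation genes, 1 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.099), and the 4 were class II genes or their chaperone: HLA-DRA (-1.15 ± 0.15), HLA-DQA1 (-1.08 ± 0.18, or -2.10 with a pseudocount of 1, ending near the floor), CD74 (-0.84 ± 0.16) and HLA-DPB1 (-0.71 ± 0.17). Of 32 interferon response genes, 5 rose and none fell (4 and 0 when adjusted over the list alone; camera adjusted p = 0.28), with XAF1 at 1.24 ± 0.23, from near the floor (2.58 with a pseudocount of 1), and ISG15 at 0.79 ± 0.16. Of 25 oxidative stress and metal response genes, 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.79), although with median centring that list passed as higher than other genes (0.09, adjusted p = 0.033; 0.033 to 0.97 over its other settings). Median centring raises bright genes by more than dim ones here, so that pass does not show a rise. Of 16 heat shock genes, DNAJB1 rose by 0.55 ± 0.13 (adjusted p = 0.0134), also when adjusted over the list alone (camera adjusted p = 0.61). Of 17 housekeeping genes, CHMP2A (0.60 ± 0.11) and VCP (0.48 ± 0.14) rose, also when adjusted over the list alone (median 0.01; camera adjusted p = 0.79), and the median was -0.15 with 2% trimmed mean scaling. The other probe set of VCP had -0.02, and without shared probe sets VCP had -0.02 (limma adjusted p = 0.95), so its rise is uncertain.

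Markers of lung epithelium, endothelium and blood mostly lay below the level needed for testing. Of 14 lung epithelium markers with a probe set, 10 lay below the level needed for testing, and of the other 4, SFTPB had -0.75 ± 0.21 (adjusted p = 0.0297; 0 rose and 2 fell when adjusted over the list alone). That fall rests on a single shared probe set: the other 3 of SFTPB had 0.10, -0.23 and -0.19, and without shared probe sets the difference was 0.10 (adjusted p = 0.8; 0.014 to 0.8 over its other settings). Of 13 endothelial markers, 9 lay below that level and none of 4 passed, also when adjusted over the list alone; ENG had 0.29 ± 0.24 (adjusted p = 0.453). Of 19 blood and immune markers, 14 lay below it and none of 5 passed, also when adjusted over the list alone (camera adjusted p = 0.50); CD79A had -0.40 ± 0.16 (adjusted p = 0.115). Of 8 fibroblast markers, which U87 cells also express in part, 4 rose and 2 fell, also when adjusted over the list alone (median 0.58; camera adjusted p = 0.12), with LUM at 1.33 ± 0.16 and PDPN at -1.72 ± 0.22; COL1A2 and LUM are also members of the collagen and matrix glycoprotein lists. Of 10 astrocyte and glia genes, 2 rose and 2 fell (3 and 2 when adjusted over the list alone; median 0.036, mean -0.004, camera adjusted p = 0.94), with SLC1A2 at 0.99 ± 0.20, from near the floor, and GLUL at -1.21 ± 0.18. Of 8 epithelial junction genes, CLDN7 rose by 0.81 ± 0.21 from near the floor (2.16 with a pseudocount of 1), also when adjusted over the list alone (camera adjusted p = 0.86).

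In all, 11 of 33 lists passed camera, 8 higher and 3 lower, and 0 passed with an estimated correlation, where 10 were at an unadjusted p below 0.05. The counts depend on the scaling and on single arrays: without scaling, 7181 genes were higher and 64 lower (median of all genes 0.63), and without U87-2M1 replicate 3, 904 genes were called, without U87 replicate 1, 1236, and without U87 replicate 3, 1157.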

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

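The tests in this part on array brightness and on the hypoxia list were chosen only after the results were seen, as were the splits of the arrays for genes and lists, the tests of the chromosome shifts against variation between arrays and against the range of draws under other scalings, and the look at array pairs within a subline; the other chromosome tests were set before.

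A signal in data outside the comparisons appeared in probe sets without a single gene name: of 4071 at or above the level needed for testing, 439 passed an adjusted p of 0.05 (limma), 200 higher and 239 lower in U87-2M1. A second such signal was that of the control probe sets for 18S ribosomal RNA, higher in the subline by 0.77 on the log2 scale beyond the arrays' trimmed means (3.31 ± 0.07 in U87 and 4.07 ± 0.65 in U87-2M1, mean ± SD, n = 3 each). Much of it came from a single array: without U87-2M1 replicate 1 the difference was 0.39. The deposited intensity of these controls had a geometric mean of 216 to 246 in U87 and of 493 to 1513 in U87-2M1, where replicate 1 was the highest.

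The U87-2M1 arrays were brighter before scaling, by 0.88 in the log2 trimmed mean. A gain of the scanner or the hybridization is argued against only weakly as the whole cause. The spike-ins added at hybridization differed by 0.24 and left an excess of 0.64 ± 0.24 (SE, n = 3 each). That excess passed a bound of 2 SE chosen after the values were seen, which is loose for so few arrays. Partly degraded RNA in the dimmer group stays open: of 2 control genes, 1 had a lower 5′ to 3′ ratio on every U87 array (GAPDH) and the other overlapped. The amount of labelled RNA and any difference in RNA content between the cells stay open as well, since nothing added before extraction was measured and both move with the group.

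The hypoxia response list was not higher in U87-2M1. Whether a rise was hidden by the scaling stays open: relative to all tested genes the list's median was -0.13 in the main setting and at most -0.03 under the 4 other scalings (the same value by construction with median centring and without scaling), but its members went both ways, with a spread of 0.34 (as large as the interquartile range divided by 2), and with median centring camera's direction turned (adjusted p = 0.99; 0.081 to 0.99 over its other settings except fry, 0.00045). That oxygen was no longer low when the subline was lysed cannot be told apart from a stable loss of the response or from a different state of the late passage parental cells, because no oxygen reading at lysis was used here and the groups differ in all 3 respects; the glycolysis list had a median of 0.001 in the main setting but passed as higher with median centring and without scaling (0.126 in both, adjusted p = 0.023 and 0.04; 0.023 to 0.98 over its other settings). That pass of glycolysis came from settings that raise bright genes by more than dim ones, so it does not bear on oxygen. Among 10 splits of the 6 arrays, 1, the real one, had an absolute list median as large as 0.154, and the highest other was 0.095; 10 splits are too few for a share under 0.05.

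Genes of some chromosomes shifted together: of 23 chromosomes, 6 had a median difference outside the range of 1000 draws matched on brightness, with 1, 16 and X higher (0.12, 0.14 and 0.10 relative to all placed genes) and 4, 10 and 13 lower (-0.19, -0.08 and -0.15). The brightness of the genes is argued against by that count of 6. All 6 kept their direction under the 4 other scalings, of which median centring and no scaling give the same relative values by construction, the bound set before, which was too weak because medians within the range of draws have a direction too. With the range drawn anew under each scaling, the scaling is argued against for 1, 4 and 16: all 3 lay outside it every time. The scaling stays open for 10, 13 and X, of which 1 did: chromosome 10, by a small margin (-0.058 against -0.052 with spike-in scaling). These sets were formed after those values were seen, so each chromosome is judged singly and the counts do not test the sets. Variation between arrays of a group is argued against only weakly for chromosomes 1, 10 and X. Their group difference was at least 2.2 times the widest range within a group. Such variation stays open for 4, 13 and 16, where the group difference was at most 1.1 times that range. These sets were formed from the ratios themselves and no bound was set before, so the ratios do not test the sets. A candidate explanation is that DNA copy number differs between the subline and the parental cells, but the test cannot tell: neighbouring genes with unlike names correlated at 0.08 (highest of 1000 shuffled orders 0.026), and pairs of U87-2M1 arrays, which should share their DNA, gave 0.0841, 0.127 and 0.205, although pairs of U87 arrays gave -0.0127 to 0.00711. The SD of the chromosome medians was 0.071 in the real split, 1 of 10 as large, and 0.055 in the highest other, again too few splits for a share under 0.05.

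Of the 10 splits, 1, the real one, gave as many as 1874 genes, 372 genes at 2-fold or 11 lists; the highest other splits gave 0, 0 and 2. Those splits are too few for a share under 0.05.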

How the results depend on the processing

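Scaling by 2% trimmed means and on spike-ins was chosen after seeing the data, whereas no scaling was the main fit of the plan and median centring a planned setting. The count of 1874 genes was 1188 to 1925 in the settings that keep quantile normalization and all arrays; 77 of 131 called named genes kept direction and call in each setting in which they were tested (43 of them in all 18, 34 in fewer), and 6 reversed in at least 1. All list reversals refer to the direction given by camera, with the list's median as value; the cause was not tested unless stated. The pseudocount compresses the differences of dim genes, and changing it moved the count at 2-fold from 372 to 716 (pseudocount 1) and 120 (pseudocount 64).

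Settings that leave the arrays' brightness unequal raise nearly every gene, by construction: the median of all genes was 0.63 without scaling, 0.51 with median centring and 0.45 with spike-in scaling, the counts of genes 7245 (7181 higher, 64 lower), 6412 (6278, 134) and 3835 (3758, 77), against 1071 and 803 in the main setting, and at 2-fold 2368, 1629 and 1296. Relative to that median, 1872, 2490 and 931 genes were called. With the pseudocount these settings also raise bright genes by more than dim ones, so a list's direction relative to that median depends on the brightness of its genes. Without scaling and with median centring alike, these lists reversed: glycolysis 0.13, matrix metalloproteinases 0.12, epithelial junction -0.27, Wnt -0.001, Notch -0.24, angiogenesis -0.092, mitosis 0.009, oxidative stress 0.085, heat shock 0.13 and astrocyte and glia -0.032, of which glycolysis passed in both (adjusted p = 0.023 with median centring, 0.04 without scaling) and oxidative stress with median centring (0.033); with median centring also the hypoxia list (-0.028, adjusted p 0.99; 0.081 to 0.99 over its settings other than fry). With spike-in scaling glycolysis 0.065, matrix metalloproteinases 0.10, epithelial junction -0.19, Notch -0.25, oxidative stress 0.025, heat shock 0.098, astrocyte and glia -0.025 and VIM -0.045 reversed. With 2% trimmed mean scaling (1996 genes) matrix metalloproteinases -0.012, epithelial junction -0.029, Notch -0.24, astrocyte and glia -0.063, housekeeping -0.15 and VIM -0.23 (adjusted p = 0.04) reversed.

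With the mean of a gene's probe sets (191 genes at 2-fold) heat shock -0.044, astrocyte and glia -0.08, RECK 0.094, PGF 0.84 and MMP2 -0.13 reversed. Without shared probe sets (1188 genes, 245 at 2-fold, fewer genes tested) epithelial junction -0.088, Notch -0.18, heat shock 0.26, housekeeping -0.02, ATP5PB 0.16, RECK 0.62, WNT7B 0.011, SFTPB 0.10 and VCP -0.02 reversed. Epithelial junction was -0.052 and astrocyte and glia -0.02 without a filter, astrocyte and glia -0.02 with pseudocount 1, and Wnt -0.078 with the filter at the 60th percentile. With an estimated correlation 0 lists passed and with fry 22, the hypoxia list (-0.15) among them, while fry turned astrocyte and glia (0.036) and oxidative stress (-0.065).

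Leaving out an array gave 904 to 2012 genes, 352 to 454 at 2-fold, 10 to 12 lists and a hypoxia median of -0.27 to -0.14. Ranges that cross a reversal were -0.076 to 0.042 for epithelial junction, -0.25 to 0.11 for astrocyte and glia, -0.035 to 0.12 for glycolysis, -0.089 to 0.039 for Wnt, -0.11 to -0.046 for oxidative stress, -0.15 to 0.17 for matrix metalloproteinases, -0.16 to 0.23 for MMP2 and -0.15 to 0.008 for CD44. The replicate block gave 1821 genes, 373 at 2-fold and 11 lists, with a hypoxia median of -0.15. Same-numbered arrays correlated at only 0.02, 0.04 and 0.03 in their deviations from the group means. Every array still correlated best with its own number, so a weak pairing by number cannot be excluded.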

Other observations

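The families in this part were found by testing 309 groups of at least 6 genes that share a symbol stem, and were named after their values were seen; 5 passed camera (Benjamini-Hochberg) and none did with an estimated correlation (adjusted p = 0.96). Pregnancy-specific glycoproteins, secreted proteins of the placenta, were higher in U87-2M1: 6 of 8 rose and none fell (median 0.78, camera adjusted p = 0.0036), with PSG2, from near the floor of the scale, at 1.38 ± 0.19 (SE) and PSG9 at 1.14 ± 0.18. Their probe sets are largely marked as shared within the family, so the count of separate genes is uncertain. All 8 lay at 4.29 to 5.00 in U87, below or not far above the level needed for testing (4.61), so the size of the rises is uncertain as well. The CXC chemokines were lower, with 4 of 6 fallen and none risen (median -0.86, camera adjusted p = 0.0007): CXCL2 had -1.13 ± 0.10, CXCL1 -1.01 ± 0.15, CXCL8 -0.87 ± 0.15 and CXCL3 -0.86 ± 0.15, against the rise of CCL2 by 3.96. Of 40 genes whose symbols start with RPL, mostly proteins of the large ribosomal subunit, 11 fell and none rose (median -0.15, camera adjusted p = 0.0007), led by RPL22L1 at -0.83 ± 0.08. Relative to all genes, these directions held under each other scaling: 0.69 to 0.73 for the pregnancy-specific glycoproteins, -0.84 to -0.80 for the chemokines and -0.33 to -0.12 for the RPL genes. The 33 genes whose symbols start with RPS did not pass as a family: 2 rose and 6 fell (median -0.077, camera adjusted p = 0.67). The RPL and RPS families were not tested against each other, so a smaller fall of the RPS genes is not excluded.

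Along the chromosomes, the stretch of 40 tested genes with the highest median, 0.45 relative to all placed genes, lay on chromosome 16 from PHLPP2 to CMIP, where 15 rose and 1 fell. On chromosome 1, the stretch from DISP1 to CCSAP had 0.39, with 12 risen and none fallen, and on chromosome 4 that from CENPC to PAQR3 had -0.34, with 2 risen and 12 fallen. Other stretches went against their chromosome. That from TADA1 to PAPPA2 on chromosome 1 had -0.26, with 0 risen and 5 fallen. That from POLR3K to CRAMP1 on chromosome 16 had a median of -0.175, with 3 risen and 0 fallen. These stretches were picked as the extremes of their chromosomes, and chromosomes 4 and 16 also varied between the arrays of U87-2M1.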
